A study of Mus musculus with 18 samples.

How the data were processed

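The caput epididymis of C57BL/6J mice, the proximal segment of the duct in which sperm mature, was profiled by RNA sequencing in 18 libraries. Samples fell into 6 groups of 3 by their labels. A control group, a 6% ethanol (EtOH) group and a 10% EtOH group were collected at 10 weeks of treatment, and a second set of the same 3 treatments was collected after cessation, which the series title puts at 1 month. How the ethanol was given, how long the cessation groups had been treated, and the ages of the mice are not given in the sources used here. The labels carry 18 different sample identifiers and do not say whether samples share a litter, cage or day, so the p-values measure the spread between these samples. Replicate numbers follow the order of deposit and pair no samples.

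The deposited values were whole-number counts of reads per gene, 1 table per library, all with the same 53819 gene entries. Per the labels, total RNA was extracted with a Qiagen RNeasy mini kit and sequenced on an Illumina HiSeq. Per the submitters' processing notes, Trimmomatic, STAR and featureCounts were used with the mouse build GRCm39 (mm39); versions, the annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Ribosomal protein genes, beta-defensins and mitochondrially encoded genes have near-identical copies or pseudogenes elsewhere in the genome, so their counts are uncertain to the extent that the counting divided such reads. Genes that overlap on opposite strands cannot be told apart without knowing the strand setting. The tables name genes by symbol, with 1442 entries named by an Ensembl identifier, and carry no coordinates. The annotation at hand was of an earlier build, so positions are not given, and it was used only for transcript length and GC content (matched by symbol for 97.2% of the tested genes and for at least 90% of the members of each list examined).

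Library totals ranged from 10.7M to 21.1M assigned reads, with a median of 16.0M. No entry was without a gene name. Replicates of a group differed by far more than sampling noise: the chi-square per degree of freedom between pairs was 5.80 or more, so none was a repeat count of the same library. This cannot show that they came from separate animals, and each was counted as a separate sample by its label. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 18618 genes holding at least 99.7% of the counts of every library. Counts were scaled by TMM (factors 0.914 to 1.20).

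Each comparison was tested with edgeR 4.0.16 (R 4.3.3), using the robust quasi-likelihood test over all 18 libraries with 1 term per group, so that the 6 groups shared an estimate of the spread. The common biological coefficient of variation was 25.4%. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 (two-sided). The 9 comparisons were each EtOH dose against control at each time, the doses against each other at each time, the difference of each dose's effect between the times, and the controls of both times against each other. Levels are TMM-normalised CPM with the SD over 3 libraries, and log2 fold changes carry the standard error implied by the test.

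Lists of genes were fixed before the data were examined. They covered oxidative phosphorylation (complex I, complexes II and III, complex IV, ATP synthase), mitochondrially encoded genes, mitochondrial ribosome, mitochondrial dynamics, mitochondrial DNA maintenance, the TCA cycle, fatty acid oxidation, stress responses (integrated stress response, unfolded protein response, heat shock), cytosolic ribosome, translation initiation and mTOR, antioxidant defence, ethanol metabolism, small RNA biogenesis, extracellular vesicles, regional secretory genes of the epididymis, beta-defensins, androgen response, cholesterol synthesis, interferon response, inflammatory cytokines, circadian clock, immediate early genes, cell cycle, hypoxia, extracellular matrix, and markers of clear and narrow cells, basal cells, smooth muscle, endothelium, fibroblasts, adipocytes, macrophages, T and NK cells, B cells, red blood cells, germ cells, ciliated cells of the efferent ducts and nerve. Of 46 lists, 44 had at least 5 tested members (marker lists of neutrophils and mast cells and of the other accessory glands had fewer) and were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) against all other genes, adjusted over the 44 lists. Each was also tested with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction. Per list, genes were also counted with p-values adjusted over the list alone.

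The genes named in the text follow a rule also fixed beforehand. Where at least 5 genes passed, these were the 10 largest rises and 10 largest falls among genes with a mean log2 CPM of at least 1 and no overlap between the groups; elsewhere the 10 genes of smallest p with that level were named as not past the threshold (5 for contrasts between doses or times). Up to 4 members of smallest p came from each list past the threshold and from the mitochondrial, stress, antioxidant, ethanol, small RNA and initial segment lists. Provisional gene names were left out.

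The share of counts in the protein-coding mitochondrially encoded genes was compared by an exact two-sided permutation test, for which 3 against 3 samples give a smallest p of 0.1. Fold changes of the doses were correlated across genes beside 100 simulated pairs of unchanged groups that shared the real controls, and those of the times beside 100 regroupings of the samples. Genes are not independent replicates, and these correlations describe the libraries as a whole.

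Alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, voom with sample quality weights, no low-count filter, a stricter filter (1 CPM in at least 9 libraries), 1 surrogate variable (sva 3.50.0), a fit of the compared groups only, and each library left out in turn. A fit of only the 9 libraries of the same time was added after the spread was seen to differ between the times. A fit with each library's trends in log2 CPM with GC content and transcript length (loess) removed through offsets was added for all comparisons after the data were seen. The share of mitochondrially encoded genes was set against each library's correlation of level with GC, both as deviations from the group means, by exact permutation within groups (46656 arrangements for the 18 libraries, 216 for the 9 of 10 weeks). It was set in the same way against the mean log2 level of the endothelium, smooth muscle, fibroblast, macrophage and matrix lists. A changed direction of a list is read from camera, a correlation was taken as unchanged within 1 jackknife standard error, a share within 1 pooled SD and a count within 1.5 times.

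The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed and each gene given the same spread in all groups. For 10% EtOH at 10 weeks (18139 simulated genes), edgeR recovered 16.4%, 56.7% and 83.3% of genes changed by 1.5, 2 and 4 times, and 5.45% of its calls were unchanged genes; the share of unchanged genes among calls was 23.5% for DESeq2 and 4% for voom. A complex I list raised 1.3 times was recovered at an adjusted p of 5.53e-26 and none of the other lists passed. These genes were drawn independently of each other. The trial therefore cannot show how often lists of correlated genes pass by chance.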

Results

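Gene expression in the caput epididymis was measured in 18 RNA sequencing libraries from mice given no ethanol, 6% EtOH or 10% EtOH. The 3 groups of 10 weeks were collected at the end of treatment, and the other 3 after cessation, with 3 libraries in each group. The series title sets these tissues beside sperm small RNAs and the mitochondria of the epididymis, so genes of mitochondria, stress responses and small RNA handling were among the lists fixed beforehand. The 9 libraries of 10 weeks held 15.6M to 21.1M assigned reads and the 9 libraries after cessation 10.7M to 17.2M. Gpx5, a secreted antioxidant enzyme of the caput under androgen control, took 1.97% to 4.73% of all counts. The 20 genes most abundant on average over the 18 libraries took 12.6% to 20.0% of a library.

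Both sets of tissue differed in the level of immediate early genes. Immediate early genes, which cells induce within minutes of a stimulus, had a mean centred log2 level between -1.46 and -0.57 in the 9 libraries of 10 weeks and between 0.10 and 2.23 in the 9 libraries after cessation, whatever the treatment. The replicates also lay closer together at 10 weeks. The biological coefficient of variation within groups was 11.6% in controls, 14.5% with 6% EtOH and 23.0% with 10% EtOH at 10 weeks, against 35.1%, 29.9% and 27.7% after cessation. It lay below the common 25.4% in every group of 10 weeks and above it in every later group. The main test used that shared estimate, so it was cautious at 10 weeks and lenient after cessation. The first principal component held 32.9% of the variance and the second 14.4%. The first did not separate the times. The libraries of 10 weeks lay on it between -41.5 and -9.98 and those after cessation between -23.5 and 91.3. Control cessation replicate 2 (-22.7) and 10% EtOH cessation replicate 1 (-23.5) lay within the range of 10 weeks. Replicate 3 of the 10% EtOH group of 10 weeks carries an identifier of another kind than the other libraries of its group. The sample label and the count table of 6% EtOH cessation replicate 1 carry different identifiers, so which animal it came from is uncertain.

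**Figure D1:**
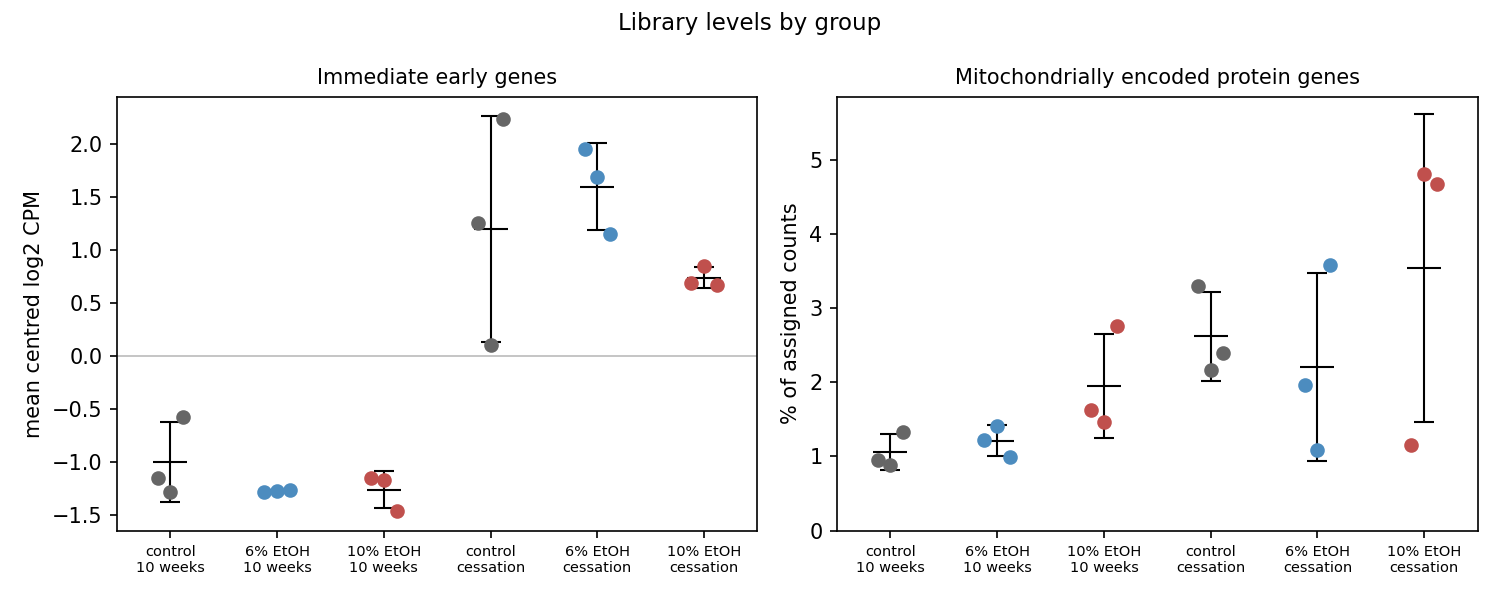
Mean centred log2 CPM of the immediate early genes (left) and percent of assigned counts in the protein-coding mitochondrially encoded genes (right) in the 6 groups; points are libraries, bars the mean ± SD, n = 3. The immediate early genes lay at -0.57 or below in all libraries of 10 weeks and at 0.10 or above in all libraries after cessation, and the mitochondrial share was 1.06% in the controls of 10 weeks and 2.62% in those after cessation.

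The first question was whether 6% EtOH for 10 weeks altered the caput. As groups, the nuclear genes of the respiratory chain and of both ribosomes rose by small amounts. Complex I subunits, which pass electrons from NADH into the chain, had a median log2 fold change of 0.16 (42 of 45 members above 0, adjusted p = 1.69e-08), complexes II and III 0.17 (17 of 21, 1.85e-05) and ATP synthase 0.14 (19 of 20, 4.89e-05). Cytosolic ribosomal proteins rose by a median of 0.12 (75 of 82, 1.00e-08) and mitochondrial ribosomal proteins by 0.14 (70 of 79, 2.67e-08), with Rps7 at 0.41 ± 0.18, Mrps23 at 0.36 ± 0.13, Ndufs6 at 0.31 ± 0.13 and Ndufb6 at 0.33 ± 0.14 among the members. Markers of adipocytes rose by 1.10 (13 of 15, 1.18e-05), with Plin1, which coats lipid droplets, at 2.70 ± 1.26 and the hormone gene Lep at 2.08 ± 1.03 (3.51 without control replicate 1); epididymal fat lies against the duct. Secretory genes of the distal caput and corpus rose by 0.29 (12 of 15, 0.00165). None of these lists passed with an estimated correlation, where adjusted p = 0.801 for the respiratory chain, mitochondrial ribosome and adipocyte lists, 0.863 for the cytosolic ribosome and 0.858 for the distal caput.

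Of the 44 lists, 17 passed with 6% EtOH at 10 weeks, 15 of them upward, and the 7 above kept their call whichever library was left out. The medians of the cytosolic and mitochondrial ribosomes fell to 0.07 and 0.09 without control replicate 3, and that of the adipocytes ranged from 0.69 without 6% EtOH replicate 3 to 1.93 without control replicate 1. The other 10 lists lost their call in at least 1 leave-out. They were complex IV (0.13, adjusted p = 0.0160), mitochondrial dynamics (0.10, 0.0139), antioxidant defence (0.08, 0.0252), fatty acid oxidation (0.05, 0.0315), initial segment genes (0.30, 0.0315), macrophages (0.22, 0.0119), fibroblasts (0.25, 0.0252), red blood cells (0.88, 0.0472), ciliated cells of the efferent ducts (-0.64, 4.79e-04) and immediate early genes (-0.24, 0.0267). Lost without control replicate 3 were complex IV (0.08), mitochondrial dynamics (0.06), antioxidant defence (0.04), fatty acid oxidation (0.01), the initial segment (0.15), macrophages (0.13), ciliated cells (-0.35) and immediate early genes (-0.03). Lost without 6% EtOH replicate 2 were complex IV (0.12), antioxidant defence (0.05), fatty acid oxidation (0.03), the initial segment (0.25), fibroblasts (0.14), macrophages (0.19), red blood cells (0.92) and immediate early genes (-0.20). Without 6% EtOH replicate 3, complex IV (0.12), fatty acid oxidation (0.04), the initial segment (0.19) and red blood cells (0.19) were lost, without control replicate 2 fibroblasts (0.13) and red blood cells (0.46), and without 6% EtOH replicate 1 immediate early genes (-0.28). Antioxidant defence lay at 0.04 without 6% EtOH replicate 3, fatty acid oxidation at 0.12 without 6% EtOH replicate 1, immediate early genes at -0.40 without control replicate 2, and red blood cells at 1.58 without control replicate 1 and 1.36 without 6% EtOH replicate 1. Without control replicate 3, 11 lists passed and without 6% EtOH replicate 2, 9 did. With each library's trends with transcript length and GC content removed, complex IV (0.11, 0.152), mitochondrial dynamics (0.11, 0.0513), antioxidant defence (0.10, 0.0513), the initial segment (0.29, 0.104) and red blood cells (0.88, 0.102) no longer passed. Fatty acid oxidation then lay at 0.10, and matrix genes passed (0.14, 0.0451). With 1 surrogate variable complex IV (0.07, 0.138), mitochondrial dynamics (0.06, 0.141), antioxidant defence (0.06, 0.0768), fatty acid oxidation (-0.00491, 0.591), the initial segment (0.14, 0.271) and immediate early genes (-0.04, 0.498) were lost. Distal caput genes then lay at 0.17, macrophages at 0.34 and ciliated cells at -0.41. Red blood cells were also lost with no low-count filter (0.91, 0.225), with RLE size factors (0.90, 0.0536) and with the 9 libraries of 10 weeks (0.89, 0.149), and immediate early genes with no filter (-0.22, 0.0759). The smallest adjusted p of any list was 0.801 with an estimated correlation and 0.827 with fry.

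No single gene passed with 6% EtOH at 10 weeks in edgeR, DESeq2 or voom (0 genes, smallest adjusted p = 1), and no member of any list passed when adjusted over the list alone. At an unadjusted p under 0.05 there were 440 genes against 931 expected, in a test whose shared spread (25.4%) exceeded that of both groups (11.6% and 14.5%). With only the 9 libraries of 10 weeks, a fit chosen after the spread of the groups had been seen, there were 1371 against 858, with none past the threshold (smallest adjusted p = 0.0721). Lrfn4, a synaptic adhesion protein gene, had the smallest p: it lay at 6.57 ± 0.66 CPM (SD, n = 3) against 10.7 ± 0.93 in controls, a log2 fold change of -0.71 ± 0.19. Kif18a, a mitotic kinesin, was next at 1.43 ± 0.40, followed by Fbxl15 (0.79 ± 0.24), the centrosomal Cdk5rap2 (-0.49 ± 0.15), the RNA-binding Mex3a (-0.57 ± 0.17), Ppie (0.52 ± 0.16), Tchh (-0.64 ± 0.20; -0.40 without 6% EtOH replicate 3), Zfp516 (-0.38 ± 0.12), Cops9 (0.52 ± 0.16) and Avpi1 (0.57 ± 0.18). Groups did not overlap for 18.7% of genes, against 10% by chance. The 6% and control libraries fitted alone gave 35 genes, and without the low-count filter 44 genes passed.

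With 10% EtOH at 10 weeks, the mitochondrially encoded genes rose. All 12 tested lay higher, with a median log2 fold change of 1.05 (adjusted p = 1.34e-05), mt-Nd3 at 1.62 ± 0.49, mt-Cytb at 1.09 ± 0.50 and mt-Nd1 at 1.07 ± 0.45. Nuclear complex I genes rose too, by a median of 0.18 (34 of 45, 2.31e-04), with Ndufb4 at 0.85 ± 0.23; Ndufb1, a complex I subunit outside the list, lay at 0.68 ± 0.15. Macrophage markers rose by 0.44 (19 of 19, 2.92e-04), with Adgre1, the F4/80 antigen, at 1.70 ± 0.61 and the lysozyme gene Lyz2 at 0.88 ± 0.36. These 3 lists kept their call whichever library was left out, but without 10% EtOH replicate 3 the median of the mitochondrially encoded genes was 0.64 and that of the macrophage markers 0.26. Without that library mt-Cytb lay at 0.72, mt-Nd1 at 0.67 and Adgre1 at 0.38, and Adgre1 was at 78.5 CPM in it against 12.8 and 15.9 CPM in the other libraries of the group. With length and GC trends removed, the median of the mitochondrially encoded genes was 0.45 (adjusted p = 0.00239). For all 3, adjusted p = 0.922 with an estimated correlation. Over all genes no member of these lists passed, and adjusted over the list alone 1 of the mitochondrially encoded genes did.

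A further 10 lists passed with 10% EtOH at 10 weeks, each losing its call in at least 1 leave-out. Genes of the initial segment and proximal caput, the most active absorbing part of the duct, rose by a median of 0.53 (14 of 16, 0.00466), with the cystatins Cst8 at 0.82 ± 0.34 and Cst11 at 0.82 ± 0.35 (0.54 without 10% EtOH replicate 3). The call was lost without control replicate 3 (0.38). Fibroblast markers rose by 0.46 (14 of 15, 0.00466) and matrix genes by 0.31 (27 of 30, 0.00488), with Pdgfra at 0.61 ± 0.22 and Fn1, fibronectin, at 0.38 ± 0.13. Without 10% EtOH replicate 2 these medians were 0.28 and 0.20, neither past the threshold, and without control replicate 2 the matrix median of 0.22 did not pass either. Ciliated cell markers fell by a median of 0.62 (15 of 17 below 0, 0.00460; Rsph1 at -0.53 ± 0.23), and the call was lost without control replicate 3 (-0.39). The mitochondrial ribosome rose by 0.11 (0.00358; Mrps22 at 0.61 ± 0.15), complexes II and III by 0.11 (0.0242), ATP synthase by 0.09 (0.0280), the cytosolic ribosome by 0.06 (0.0320), mitochondrial dynamics by 0.15 (0.0485) and the unfolded protein response by 0.12 (0.0237; the ER chaperone gene Dnajb9 at 0.58 ± 0.16). The matrix, unfolded protein response and cytosolic ribosome lists had an adjusted p = 0.928 with an estimated correlation and the rest 0.922. Of the 44 lists 13 passed, 5 without 10% EtOH replicate 2 and 6 without control replicate 3. In the order above, the last 6 lists lay at 0.05, 0.10, 0.05, 0.01, 0.16 and 0.10 without control replicate 3 and at 0.06, 0.06, 0.03, -0.04, 0.11 and 0.08 without 10% EtOH replicate 2, none past the threshold. Without 10% EtOH replicate 1, complexes II and III (0.09), ATP synthase (0.04), the cytosolic ribosome (0.03) and mitochondrial dynamics (0.14) were lost, and without control replicate 1 mitochondrial dynamics (0.13). Complexes II and III lay at 0.18 and the cytosolic ribosome at 0.15 without 10% EtOH replicate 3. With length and GC trends removed, mitochondrial dynamics no longer passed (0.06, 0.538) and the interferon response did (0.22, 0.0286). The cytosolic ribosome then lay at 0.12 (0.00794), ATP synthase at 0.11 (0.0320) and complexes II and III at 0.07 (0.0393). With 1 surrogate variable complexes II and III (0.10, 0.140), ATP synthase (0.04, 0.217), the cytosolic ribosome (0.04, 0.199), mitochondrial dynamics (0.12, 0.266) and the unfolded protein response (0.05, 0.334) were lost. With a stricter filter the cytosolic ribosome (0.05, 0.0517) and mitochondrial dynamics (0.15, 0.0653) were lost.

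Of the lists of stress responses, the integrated stress response and heat shock did not pass with 10% EtOH at 10 weeks, nor did those of RNA handling and metabolism. The integrated stress response, the translational programme that mitochondrial damage can switch on, lay lower at a median of -0.31 (20 of 29 members below 0, adjusted p = 0.0530; Mthfd2 at -0.51 ± 0.18, or -0.31 without 10% EtOH replicate 3), and heat shock at 0.01 (0.865). Small RNA biogenesis lay at -0.04 (0.627), with the Argonaute gene Ago1 at -0.41 ± 0.14, and the extracellular vesicle pathway at 0.01 (0.309). Ethanol and aldehyde metabolism lay at 0.10 (0.997) and antioxidant defence at -0.02 (0.863), although the antioxidant members Gpx4 (0.61 ± 0.16) and Prdx1 (0.60 ± 0.17) lay higher and Akr1b8 (-1.11 ± 0.41) lower. Complex IV (-0.03, 0.325), fatty acid oxidation (0.02, 0.590), the TCA cycle (-0.06, 0.844), mitochondrial DNA maintenance (0.00, 0.799), translation initiation and mTOR (-0.02, 0.978), cholesterol synthesis (0.09, 0.299), androgen response (0.13, 0.288) and nerve markers (-0.22, 0.407) did not pass either.

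Single genes of the 10% EtOH group at 10 weeks did not pass in edgeR with all 18 libraries (0 genes, smallest adjusted p = 0.274), yet 2501 had an unadjusted p under 0.05 (1274 higher, 1227 lower) where chance gives 931. Groups did not overlap for 30.7% of genes, against 10% by chance. Lrfn4 was again first, at 4.99 ± 0.79 CPM (SD, n = 3) against 10.7 ± 0.93 in controls (log2 fold change -1.10 ± 0.19, adjusted p = 0.274). Tchh (-1.01 ± 0.20), Mex3a (-0.86 ± 0.17), the actin bundler Espn (-0.91 ± 0.20), Iqsec1 (-0.85 ± 0.19), the G protein subunit Gnao1 (-0.98 ± 0.22), Foxk1 (-0.50 ± 0.11), Mbd6 (-0.66 ± 0.15) and Zfp516 (-0.52 ± 0.12) lay lower and Ndufb1 higher, each at an adjusted p of 0.299.

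Other tools and fits did pass genes in this comparison: DESeq2 73 (34 higher, 39 lower), voom 1345 (674 higher, 671 lower), edgeR with no low-count filter 736 and edgeR with only the 9 libraries of 10 weeks 1059 (672 higher, 387 lower). The last fit, chosen after the data were seen, shared 754 genes with voom, all in the same direction, and 72 of the 73 DESeq2 genes were in both. These fits used the same control and 10% EtOH libraries, so shared genes and directions are not independent support. Of the 17154 genes tested in the fit of the 9 libraries, 1059 passed. They included 6 of 20 ATP synthase members, 8 of 45 complex I members and 11 of 82 cytosolic ribosome members, all higher. Higher too were 6 of 16 initial segment members and 5 of 30 members of the unfolded protein response. The same held for 5 of 15 distal caput, 6 of 24 mitochondrial dynamics and 5 of 21 complex II and III members. Among the lists with no member past the threshold were fatty acid oxidation (28 members), interferon response (34), circadian clock (19), endothelium (16) and cell cycle (31). At 1059 of 17154 genes, lists of this size would hold few such members by chance, so their absence says little. Among single genes, Atp5md lay at 0.96 (adjusted p = 0.00643), the translocon gene Sec61b at 0.73 (0.00643) and Cox6c at 0.83 (0.0135). Ndufb1 (0.00989) was higher as well, and Lrfn4, Mex3a, Foxk1 and Mbd6 were lower (each 0.0228). The count of 1059 rested on the controls. It was 0 without control replicate 1 or 3 and 14 without control replicate 2. It was 352 without 6% EtOH replicate 2, 508 without 6% EtOH replicate 3 and 911 without 10% EtOH replicate 3, of which 744 were among the 1059. The genes followed GC content: the median was 43.0% in the higher and 55.3% in the lower genes, against 49.4% in all genes. Of the 1024 with a known length and GC content 647 were higher and 377 lower, and with length and GC trends removed 324 genes passed in this fit, 275 higher and 49 lower. The control and 10% libraries fitted alone gave 0 genes.

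The share of counts in mitochondrially encoded protein genes is relative to all other counts of a library. It was 1.95% ± 0.71 (SD, n = 3) with 10% EtOH at 10 weeks and 1.06% ± 0.24 in controls. The difference was 0.90 percentage points (exact permutation test, two-sided, p = 0.1, the smallest these groups allow, and 0.25 adjusted over 5 such comparisons). The 3 libraries held 1.63%, 1.47% and 2.76%, the highest being replicate 3. Without it the difference was 0.493 percentage points. With 6% EtOH the share was 1.21% ± 0.21 (exact p = 0.4), a difference of 0.156 that ran from 0.0552 without 6% EtOH replicate 2 to 0.295 without control replicate 3. Among libraries of the same group the share was higher where the level of genes correlated less with their GC content. As deviations from the group means, both measures correlated at r = -0.80 over the 18 libraries (exact permutation within groups, two-sided, p = 0.00894; rho = -0.82, p = 0.0132; each 0.0247 adjusted over 4 tests). Over the 9 libraries of 10 weeks r was -0.97 (exact p = 0.0185, adjusted 0.0247; rho = -0.97, exact p = 0.0324, adjusted 0.0324). Without the 2 libraries farthest out in GC trend r was -0.73 and -0.84. After cessation the share was 2.62% ± 0.60 in controls, 2.21% ± 1.27 with 6% EtOH (exact p = 0.7) and 3.54% ± 2.08 with 10% EtOH (exact p = 0.4). The libraries held 3.31%, 2.17% and 2.39%, then 1.97%, 1.08% and 3.58%, and then 1.15%, 4.81% and 4.67%. The difference for 6% EtOH, -0.415 percentage points, was 0.15 without 6% EtOH replicate 2, -1.10 without 6% EtOH replicate 3, -0.0728 without control replicate 1 and -0.640 without control replicate 2. That for 10% EtOH, 0.920, was 2.12 without 10% EtOH replicate 1, 0.287 without replicate 2 and 0.355 without replicate 3.

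**Figure D2:**
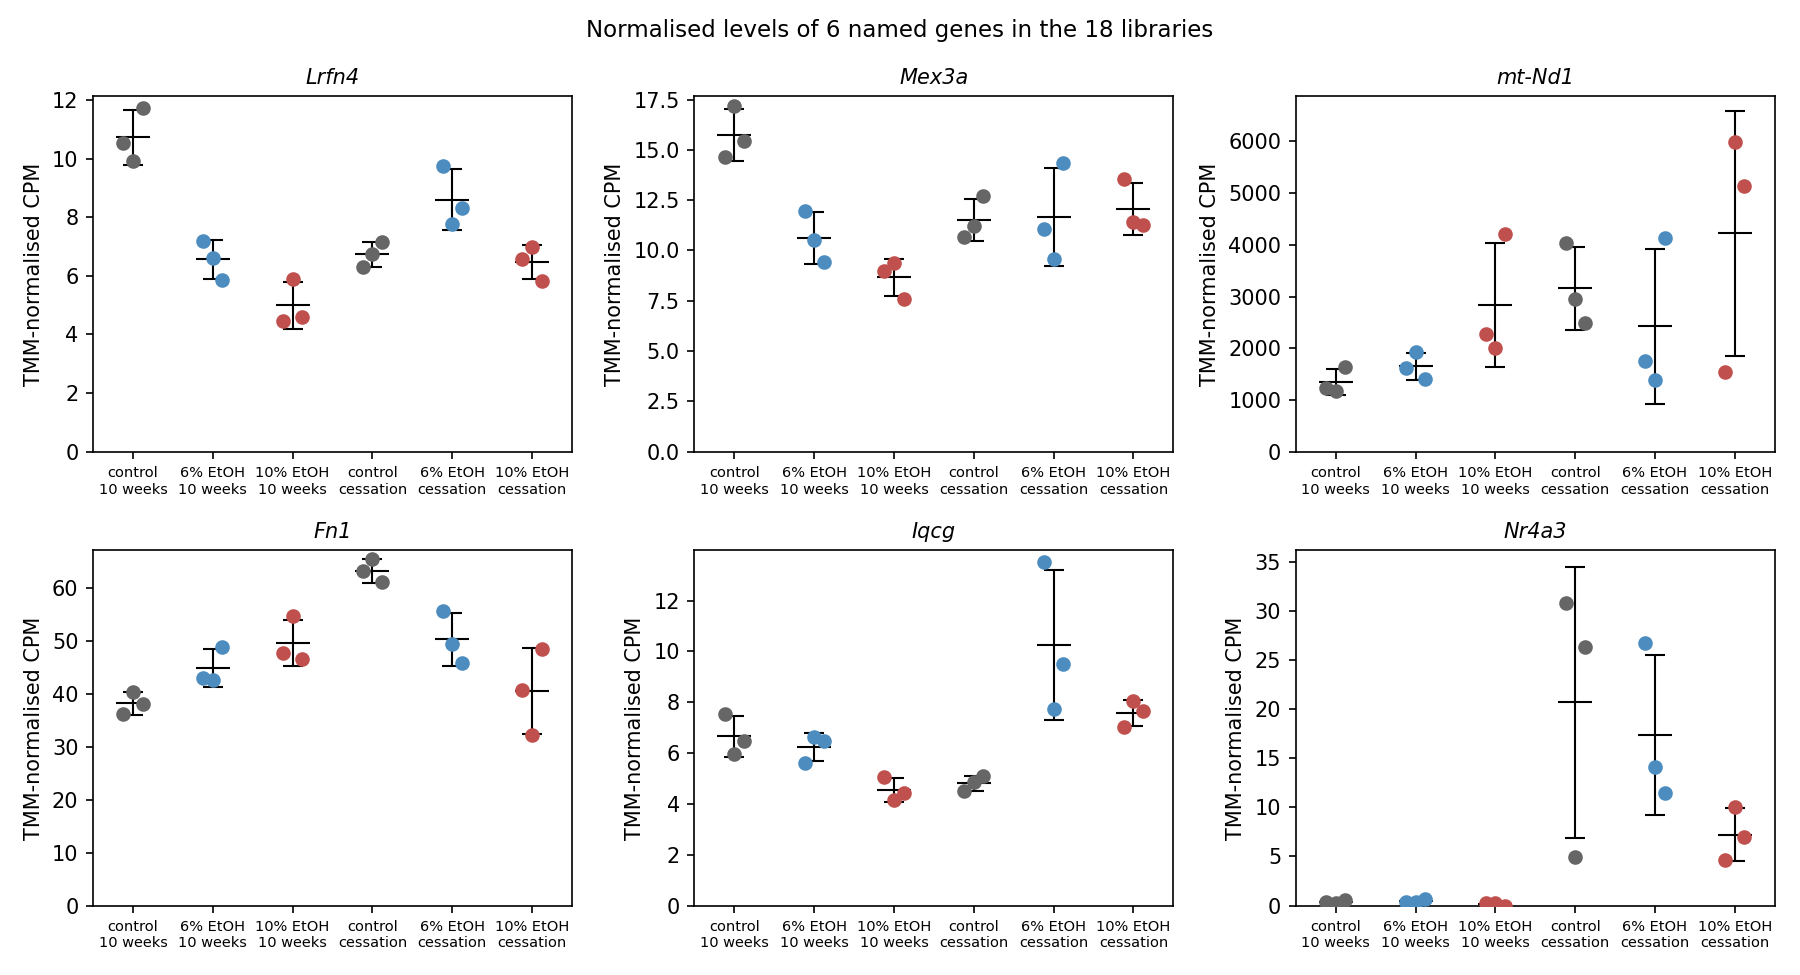
TMM-normalised CPM of 6 genes in the 18 libraries by group; points are libraries, bars the mean ± SD, n = 3, and each axis starts at 0. Lrfn4 lay at 10.7 CPM in the controls of 10 weeks and at 6.57 and 4.99 with 6% and 10% EtOH, and the immediate early gene Nr4a3 lay at 0.371 CPM in the controls of 10 weeks and 20.7 in those after cessation.

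Whether the doses moved the same genes at 10 weeks was asked across all genes. Their log2 fold changes against the shared controls correlated at r = 0.650 (rho = 0.654), and 76.2% had the same sign. Unchanged groups simulated against the same controls gave a mean r of 0.485 (range -0.06 to 0.95) and 66.0% of the same sign. The covariance was 0.122 against 0.0580 simulated, a difference of 0.0639, and 12 of 100 draws reached it. With 3 controls the comparison could not be repeated on separate controls, and part of the excess over 0 comes with the shared ones.

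Set directly against 6% EtOH at 10 weeks, the 10% group had higher mitochondrially encoded genes (median 0.77, 12 of 12, adjusted p = 8.18e-06) and lower adipocyte markers (-1.06, 1.58e-05). Both kept their call whichever library was left out, though the mitochondrial median was 0.37 without 10% EtOH replicate 3 and the adipocyte median ran from -2.17 without that library to -0.53 without 6% EtOH replicate 3. Red blood cell markers (-1.51, 0.00139), lost without 6% EtOH replicate 3 (-0.56), fell as well. The interferon response (0.27, 0.00969), macrophages (0.25, 0.0176) and matrix genes (0.23, 0.0243) rose, all 3 losing their call without 6% EtOH replicate 1 (0.17, 0.15 and 0.17). Without 10% EtOH replicate 3 the interferon (0.14) and macrophage (0.03) calls were lost, and without 10% EtOH replicate 2 the interferon (0.24) and matrix (0.11) calls. All 6 had an adjusted p = 0.981 with an estimated correlation. Of single genes 0 passed in edgeR, DESeq2 and voom, with 527 at an unadjusted p under 0.05, among them Zfp791 (0.63), the vesicular monoamine transporter Slc18a2 (1.46; 0.96 without 10% EtOH replicate 3), Rpf2 (0.78), Vps35l (-0.41) and Ido2 (-0.59), each at an adjusted p of 0.994. No low-count filter gave 60.

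After cessation of 6% EtOH, markers of ciliated cells, which line the efferent ducts that open into the caput, rose by a median log2 of 1.14 (17 of 17 higher, adjusted p = 1.61e-15). Ccdc40 lay at 1.62 ± 0.56 and Rsph4a at 1.55 ± 0.61, both building parts of motile cilia. Adipocyte markers rose by 1.27 (13 of 15, 1.52e-06), with Cfd, adipsin, at 5.17 ± 1.79 and Adipoq, adiponectin, at 3.04 ± 1.31. Both lists kept their call whichever library was left out, but the ciliated median was 0.34 without 6% EtOH replicate 1 and 0.76 without control replicate 2, and the adipocyte median 0.44 without 6% EtOH replicate 2, 0.47 with a stricter filter and 0.56 with the 9 libraries after cessation. Replicate 1, the library of uncertain identity, also weighed on the named genes. Without it Ccdc40 lay at 0.84 and Rsph4a at 0.66, while Rsph4a lay at 2.45 without control replicate 3. Adjusted p = 0.375 for both with an estimated correlation. No member passed over all genes, and 1 adipocyte gene and 0 ciliated genes passed over the list alone.

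The other 10 lists that passed after cessation of 6% EtOH each depended on single libraries. T and NK cell markers fell by a median of 0.91 (17 of 17 lower, 1.52e-06; the granzyme gene Gzma at -2.25 ± 0.98) and the interferon response by 0.43 (30 of 34 lower, 1.52e-06; Gbp2 at -1.58 ± 0.67, Stat2 at -0.44 ± 0.14). Without control replicate 1 these medians were -0.13 and 0.03, neither past the threshold, and those of the macrophages (-0.29, 0.00406) and fibroblasts (-0.24, 0.0194) turned to 0.09 and 0.04. Gzma and Gbp2 lay at -1.33 and -0.61 without that library. The unfolded protein response (-0.10, 7.96e-04) turned to 0.11 without control replicate 2 and the immediate early genes (0.15, 5.55e-04) to -0.20. Cell cycle genes (-0.14, 7.96e-04; Ccna2 at -1.31 ± 0.42) lost their call without control replicate 2 (-0.06) and the integrated stress response (-0.21, 0.00166) without control replicate 3 (-0.03). The median of the mitochondrially encoded genes (-0.23, 0.00817) was 0.11 without 6% EtOH replicate 2, though their direction in camera did not change. The beta-defensins (-0.19, 0.0210) turned to 0.12 without 6% EtOH replicate 1. Calls were also lost without 6% EtOH replicate 3 for the interferon response (-0.25), integrated stress response (-0.18), macrophages (-0.14) and fibroblasts (-0.15), without control replicate 3 for macrophages (-0.27) and fibroblasts (-0.18), and without 6% EtOH replicate 2 for fibroblasts (-0.02). Without 6% EtOH replicate 1 the unfolded protein response turned to 0.03. The immediate early median was then -0.05, though its direction in camera did not change, and the mitochondrially encoded genes (-0.10) were lost. The last were lost without control replicate 1 too (-0.02), as were the beta-defensins (-0.10), also lost without control replicate 2 (-0.09) and with length and GC trends removed (-0.12, 0.404), 1 surrogate variable (-0.16, 0.134) or no low-count filter (-0.16, 0.285). No filter also ended the call of the fibroblasts (-0.24, 0.0628). The unfolded protein response lay at -0.05 with 1 surrogate variable and the immediate early genes at 0.10 with a stricter filter. Without 6% EtOH replicate 2, 6% EtOH replicate 1 or control replicate 3, the number of lists past the threshold was 22, 20 and 20, against 12 with all. No list passed with an estimated correlation, the smallest adjusted p being 0.375, or with fry (0.934). Complex I lay at 0.00 (0.820).

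No gene passed after cessation of 6% EtOH in edgeR or voom, and 1 did in DESeq2; 301 genes had an unadjusted p under 0.05 and the smallest adjusted p was 1. Iqcg, a ciliary gene, came first at 10.3 CPM against 4.82 in controls (log2 fold change 1.09 ± 0.22). Plin4 (0.55 ± 0.14) lay higher, and Siah1a (-0.59 ± 0.15), Dclk1 (-1.54 ± 0.42), the interferon-induced chemokine gene Cxcl9 (-4.02 ± 1.13; -2.31 without control replicate 1, at 21.5 CPM against 0.614 and 4.89 CPM in the other controls) and the antiprotease gene Wfdc13 (-4.96 ± 1.53) lower. Groups did not overlap for 4.01% of genes, against 10% by chance. Without the low-count filter 51 genes passed. With only the 9 libraries after cessation, 123 genes had an unadjusted p under 0.05 against 886 expected, and none passed.

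After cessation of 10% EtOH, the interferon response fell by a median of 0.80 (33 of 34 lower, adjusted p = 3.84e-12), with Gbp2 at -2.80 ± 0.71 and Bst2, tetherin, at -1.09 ± 0.28. Basal cell markers fell by 0.46 (10 of 11, 5.62e-08), with Krt17 at -2.01 ± 0.46 and Itgb4, an integrin that anchors cells to the basement membrane, at -1.02 ± 0.30; the laminin gene Lamb3, outside the list, lay at -1.21 ± 0.29. T and NK cell markers fell by 1.54 (16 of 17, 6.51e-07; Ccl5 at -2.24 ± 0.68), inflammatory cytokines by 0.92 (22 of 24, 2.37e-04), hypoxia and glycolysis genes by 0.23 (24 of 29, 4.78e-05; Hk2 at -0.93 ± 0.23), clear cells, which acidify the lumen, by 0.21 (9 of 11, 6.58e-04; the proton pump gene Atp6v0a4 at -0.91 ± 0.29) and the integrated stress response by 0.16 (18 of 29, 0.00189). In the last, Ddit3 (-3.02 ± 0.70), Atf3 (-2.08 ± 0.57) and Atf4 (-0.90 ± 0.24), its transcription factors, lay lower. Over the list alone 5 interferon, 6 basal, 6 stress response and 1 hypoxia genes passed, all lower, and over all genes 0. With an estimated correlation, adjusted p = 0.604 for the interferon, cytokine and stress lists, 0.468 for the basal, T and NK and clear cell lists and 0.585 for hypoxia.

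These 7 of the 22 lists that passed after cessation of 10% EtOH kept their call whichever library was left out, with medians that moved. Without control replicate 1 the interferon median was -0.41 and that of the T and NK markers -0.55. Without control replicate 3 the cytokine median was -0.25 and the basal median -0.29. Leaving out control replicate 3 brought Ddit3 to -1.59, Atf3 to -0.79, Atf4 to -0.38, Krt17 to -0.95, Lamb3 to -0.78 and Itgb4 to -0.67. Leaving out control replicate 1 brought Gbp2 to -1.82 and Ccl5 to -1.14. With length and GC trends removed these 7 lists still passed, the hypoxia median being -0.10 and that of the stress list -0.05. With 1 surrogate variable the cytokines no longer passed (-0.25, 0.0824) and the interferon median was -0.46. Basal cells lay at -0.94 with no low-count filter and T and NK cells at -0.87 with a stricter one. Without control replicate 2 the cytokines lay at -1.40 and the basal markers at -0.92. Without 10% EtOH replicate 1 the basal, clear cell, stress and cytokine medians were -0.87, -0.42, -0.35 and -0.48, without 10% EtOH replicate 2 clear cells lay at -0.37 and the stress list at -0.11, and the hypoxia median was -0.15 without control replicate 3 and -0.13 without 10% EtOH replicate 3. The control libraries held immediate early gene levels of 1.25, 0.10 and 2.23 and the 10% EtOH libraries 0.69, 0.85 and 0.67, and the immediate early genes themselves lay at a median of -0.58 (8.48e-05), which became 0.03 without control replicate 3.

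The remaining lists past the threshold after cessation of 10% EtOH lost their call in at least 1 leave-out. Endothelium (-1.09, 3.92e-05; Sox17 at -1.78 ± 0.68, or -1.05 without control replicate 3), smooth muscle (-0.59, 0.0120), germ cells (-0.48, 0.00408), the clock (-0.19, 0.00334), heat shock (-0.06, 0.0229) and matrix genes (-0.29, 0.00218) fell, and each was lost without control replicate 3, at -0.26, -0.12, -0.06, -0.02, -0.01 and -0.15. Without 10% EtOH replicate 1, smooth muscle (-0.35), germ cells (-0.26) and matrix genes (-0.16) were lost as well, without control replicate 1 smooth muscle (-0.53) and matrix genes (-0.06), and without 10% EtOH replicate 3 heat shock (-0.02). With 1 surrogate variable in the fit the matrix median turned to 0.17 (0.0374) and that of smooth muscle to 0.14 (0.537). Also lost with it were immediate early genes (-0.10, 0.269), endothelium (-0.09, 0.537), germ cells (-0.15, 0.325), macrophages (-0.22, 0.265), beta-defensins (0.24, 0.265), distal caput genes (0.11, 0.590) and the mitochondrial ribosome (0.01, 0.708), while heat shock lay at -0.15, androgen response at -0.11 and the clock at -0.07. Macrophages (-0.47, 0.00109) were lost without control replicate 1 (-0.10) or 10% EtOH replicate 1 (-0.33), cell cycle (-0.34, 0.00408) without control replicate 2 (-0.10) and androgen response (-0.20, 0.0318) without 10% EtOH replicate 3 (-0.10) or control replicate 2 (-0.22). Beta-defensins (0.34, 23 of 28, 0.00375), distal caput genes (0.21, 0.0180), the mitochondrial ribosome (0.08, 0.00409), B cells (0.80, 0.0318) and mitochondrially encoded genes (0.52, 0.0385) rose; without control replicate 3 the first 2 were lost (0.23 and 0.03), and without control replicate 1 the mitochondrial ribosome (0.05) and B cells (1.16). The mitochondrial ribosome was also lost without 10% EtOH replicate 1 (0.07), and B cells without control replicates 2 (0.97) and 3 (0.69) and 10% EtOH replicates 2 (0.83) and 3 (0.38). No low-count filter (0.62, 0.140) or a stricter one (0.97, 0.135) ended the call of the B cells too. The mitochondrially encoded genes were lost without control replicates 2 (0.45) and 3 (0.38) and 10% EtOH replicates 2 (0.19) and 3 (0.31), and with RLE size factors (0.54, 0.0520). No list passed with an estimated correlation (smallest adjusted p = 0.468) or with fry (0.264), and complex I lay at 0.04 (0.0572) and the cytosolic ribosome at 0.02 (0.236). With length and GC trends removed both passed, at 0.11 (0.00613) and 0.10 (0.00593), and the mitochondrially encoded genes no longer did (0.14, 0.772). Immediate early genes then lay at -0.37, smooth muscle at -0.38, macrophages at -0.31, matrix genes at -0.20 and androgen response at -0.09.

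No gene passed after cessation of 10% EtOH in edgeR (0 genes, smallest adjusted p = 0.721) or DESeq2, and 66 did with voom (25 higher, 41 lower). There were 1240 genes at an unadjusted p under 0.05, 296 higher and 944 lower, against 931 expected. With only the 9 libraries after cessation there were 467 against 886, with none past the threshold. Casz1 came first (-0.73 ± 0.14), then Fn1 at 40.5 CPM against 63.2 in controls (-0.64 ± 0.13), Apoc1 (-1.06 ± 0.23), the ER stress gene Herpud1 (-0.97 ± 0.22; -0.57 without control replicate 3), Krt17, Arhgap33 (-1.07 ± 0.26), Ddit3, Lamb3, Hk2 and, higher, Cep19 (0.66 ± 0.16). Groups did not overlap for 6.46% of genes, against 10% by chance. Without control replicate 2, the control library of lowest immediate early gene level, 191 genes passed, 12 higher and 179 lower, and without the low-count filter 407 did.

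**Figure D3:**
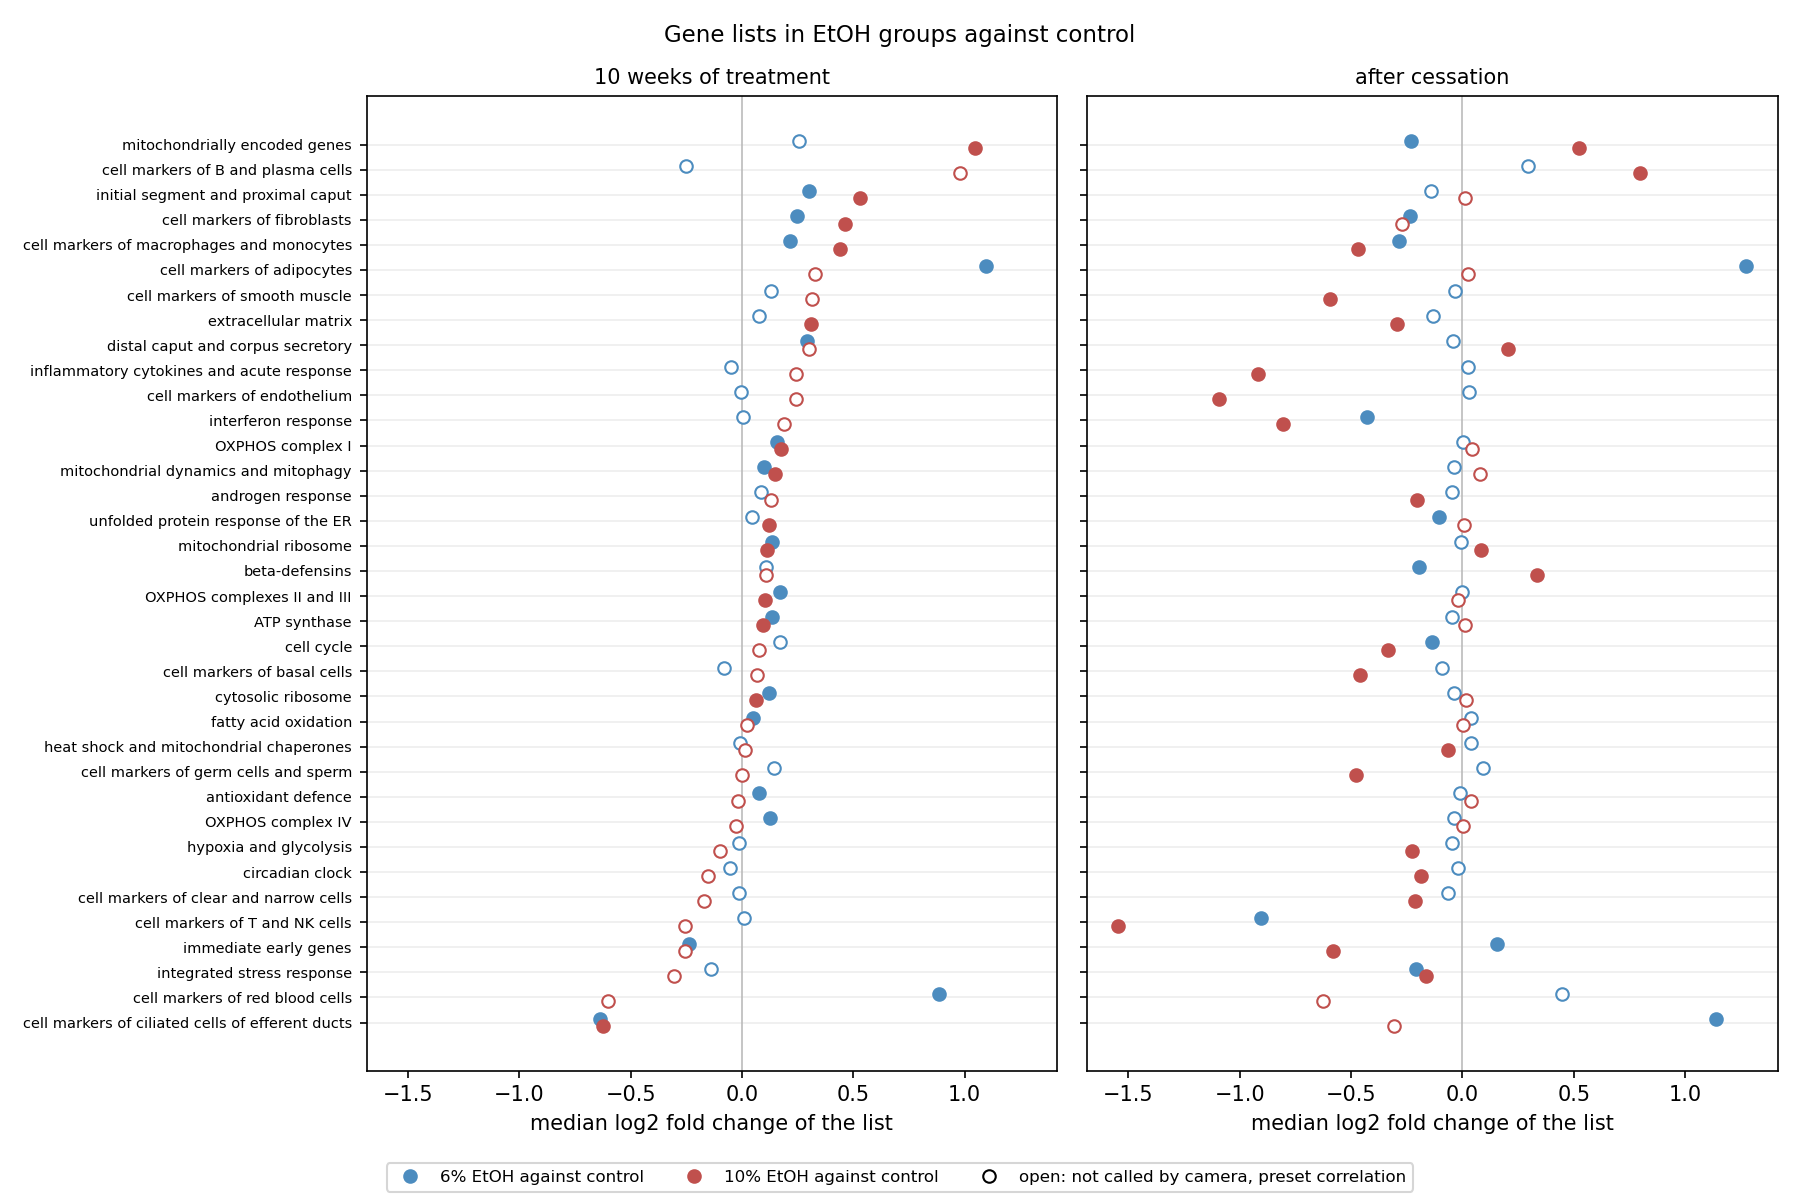
Median log2 fold change of each gene list that passed in at least 1 of the comparisons shown, for 6% EtOH (blue) and 10% EtOH (red) against control at 10 weeks (left) and after cessation (right). Each point is a list, filled where camera with the preset correlation passed and open where it did not. The mitochondrially encoded genes lay at 1.05 with 10% EtOH at 10 weeks, and the ciliated cell markers at -0.64 with 6% EtOH at 10 weeks and 1.14 after cessation.

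Between the doses after cessation, 10% EtOH had lower immediate early genes (median -0.80, 25 of 26 lower, adjusted p = 8.05e-11), ciliated cell markers (-1.32, 16 of 17, 3.05e-09) and basal cell markers (-0.45) than 6% EtOH, and higher beta-defensins (0.49, 9.60e-06). Of 23 lists past the threshold these 4 were among 7 that kept their call whichever library was left out; the ciliated median was -0.57 without 6% EtOH replicate 1, the library of uncertain identity. Endothelial markers (-1.12, 2.57e-05) lost their call without that library (-0.46). With an estimated correlation no list passed (smallest adjusted p = 0.598), and over the list alone 10 ciliated genes passed, all lower. Of single genes 0 passed in edgeR and voom and 1 in DESeq2, with 1462 at an unadjusted p under 0.05, among them Zfp276 (-0.62), the immediate early gene Arc (-1.86), Wfdc13 (6.71), Pate2 (3.80; 2.48 without 10% EtOH replicate 3) and Adsl (-0.55), each at an adjusted p of 0.634; no low-count filter gave 585. Across all genes the effects of the doses after cessation correlated at r = 0.279 (rho = 0.228, 57.0% of the same sign), below the mean of 0.448 for unchanged groups simulated against the same controls, and the covariance of 0.0426 lay below the simulated 0.0927 (difference -0.0501, reached by 54 of 100 draws). The r was 0.623 without control replicate 2 and 0.0644 without 6% EtOH replicate 3.

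Whether the effect of a dose differed between 10 weeks and after cessation was tested as the difference between the times. A difference that did not pass would not show that an effect lasted, and one that passed may come from the later libraries alone. The length of treatment before cessation is not given, so the times may differ in exposure too. For 6% EtOH, ciliated cell markers differed by a median log2 of 1.76 (adjusted p = 3.18e-13) and the cytosolic ribosome by -0.14 (1.05e-06), and both kept their call whichever library was left out, at 0.80 and -0.08 without 6% EtOH cessation replicate 1; the ribosome lay at -0.27 without 6% EtOH cessation replicate 2 and at -0.09 without control replicate 3 of 10 weeks. Complex I (-0.16, 9.19e-05) and the mitochondrial ribosome (-0.17, 9.19e-05) also differed, and both were lost without 6% EtOH cessation replicate 1 (-0.12 and -0.07). The mitochondrial ribosome was also lost without control cessation replicate 2 (-0.09), and complex I lay at -0.28 without 6% EtOH cessation replicate 2. In all 19 lists passed for 6% EtOH, with 0 passing with an estimated correlation (smallest adjusted p = 0.785). For 10% EtOH 14 lists passed, among them the interferon response (-1.04, 6.04e-11), macrophages (-0.90, 3.01e-08), matrix genes (-0.72, 4.53e-06), basal cells (-0.56) and endothelium (-1.22), and the smallest adjusted p with an estimated correlation was 0.538. The first 4 kept their call throughout; without control cessation replicate 1 the interferon median was -0.58 and the matrix median -0.46, and without control cessation replicate 3 the basal, matrix and endothelial medians were -0.20, -0.40 and -0.62, the last not past the threshold. Without 10% EtOH cessation replicate 1 the matrix median was -0.45. Over the list alone 7 interferon genes passed, all lower.

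In edgeR no single gene's effect passed for a difference between the times. For 6% EtOH, 0 genes passed in edgeR, DESeq2 and voom and 561 had an unadjusted p under 0.05, among them Lrfn4 (1.06 ± 0.26), Iqcg (1.19 ± 0.30) and Ndufb1 (-0.75 ± 0.22), each at an adjusted p of 1. For 10% EtOH, 0 passed in edgeR, 2 in DESeq2 and 4 in voom, with 1386 at an unadjusted p under 0.05, among them Fn1 (-1.02 ± 0.19), Tchh (1.35 ± 0.28), Apoc1 (-1.52 ± 0.33), the integrin gene Itga6 (-0.89 ± 0.20) and Tchhl1 (2.40 ± 0.56), each at 0.645. Without the low-count filter 88 and 385 genes passed. Across all genes the effect of 6% EtOH at 10 weeks and after cessation correlated at r = -0.136 (rho = -0.179; permutation p = 0.24 and 0.19) and that of 10% EtOH at r = 0.0967 (rho = 0.128; permutation p = 0.63 and 0.51), over 100 regroupings each. Adjusted over these 4 tests, p was 0.48 for 6% EtOH and 0.63 for 10% EtOH. For 6% EtOH r was 0.0111 without 6% EtOH cessation replicate 1. For 10% EtOH it was 0.213 without 10% EtOH cessation replicate 1, -0.0565 without 10% EtOH cessation replicate 2 and -0.0183 without control cessation replicate 3.

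The controls of both times were compared to see what changed without ethanol. Immediate early and inflammatory genes were far higher in the later controls: Nr4a3, an orphan nuclear receptor of the immediate early set, rose from 0.371 to 20.7 CPM (log2 fold change 5.78 ± 0.71, adjusted p = 0.00338), the chemokine gene Cxcl1 by 5.76 ± 1.04 (0.0447), the stress factor Atf3 by 5.29 ± 0.67 (0.00512) and the cytokine gene Il1b by 4.85 ± 0.69 (0.00935). Gadd45b (4.76 ± 0.70), the cytokine signalling inhibitor Socs3 (4.72 ± 0.70), the matrix gene Thbs1 (4.62 ± 0.80), Apold1 (4.50 ± 0.73), Rnd1 (4.49 ± 0.80), Maff (4.17 ± 0.74), the phosphatase gene Dusp1 (3.82 ± 0.58) and Fn1 (0.73 ± 0.13) also rose. In all 22 genes passed, all higher, and groups did not overlap for 25.1% of genes, against 10% by chance. The count was 1, 0 and 10 without control replicates 1, 2 and 3 of 10 weeks, and 11, 2724 and 6 without control replicates 1, 2 and 3 after cessation. DESeq2 passed 993 genes, voom 7336 and edgeR without the low-count filter 1740, whereas 5 passed with 1 surrogate variable and 0 with the 6 control libraries fitted alone.

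Immediate early genes as a list rose by a median of 2.02 in the later controls (25 of 26 higher, adjusted p = 2.42e-30), inflammatory cytokines by 2.14 (22 of 24, 1.21e-15) and matrix genes by 0.98 (30 of 30, 1.98e-12). Over all genes 9, 3 and 2 members passed and over the list alone 24, 16 and 19 higher, with 1 immediate early gene lower. The interferon response rose by 1.08 (1.94e-09), macrophages by 0.90 (1.53e-08), endothelium by 1.57 (5.97e-07), smooth muscle by 1.63 (5.28e-06), germ cells by 0.73 (4.18e-05), fibroblasts by 0.86 (1.67e-04), mitochondrially encoded genes by 1.29 (12 of 12, 5.97e-07) and T and NK cells by 1.23 (0.00607), while fatty acid oxidation (-0.17, 3.26e-04), cholesterol synthesis (-0.24, 4.53e-04) and the TCA cycle (-0.17, 0.0282) fell. Of 15 lists 11 kept their call whichever library was left out. Basal cells (0.38, 0.0171), cholesterol synthesis and the TCA cycle were lost without control cessation replicate 3 (0.05, -0.05 and -0.12), without which the immediate early median was 1.28 and the endothelial 0.85. T and NK cells were lost without control cessation replicate 1 (0.07), without which the interferon, macrophage and fibroblast medians were 0.55, 0.54 and 0.50. Without control cessation replicate 2, cholesterol synthesis lay at -0.61, fatty acid oxidation at -0.31 and basal cells at 0.60, and without control cessation replicate 3 fatty acid oxidation lay at -0.11. With an estimated correlation, adjusted p = 0.201 for the immediate early and inflammatory lists and 0.68 or more for the others, and with fry these 2 lists passed (0.0226 each). With length and GC trends removed, 46 genes and 23 lists passed, 8 of them gained and none lost, among the gained complex I (-0.16, 0.0204, from -0.01) and the mitochondrial ribosome (-0.23, 9.18e-04, from -0.10). The mitochondrially encoded genes then lay at 0.75, fatty acid oxidation at -0.27 and basal cells at 0.23. The share of counts in mitochondrially encoded genes lay 1.57 percentage points higher in the later controls (exact permutation test, two-sided, p = 0.1, the smallest these groups allow).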

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

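The tests of the difference between times were planned; those of length and GC content, the GC trend of the libraries, handling, single libraries, stromal cells, shared controls, abundant genes and tissue state were chosen after the results were seen.

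Lists that passed at both times, on opposite sides of 0, and whose difference between times passed too, numbered 6. For 6% EtOH, ciliated cell markers went from a median log2 fold change of -0.64 to 1.14 (median difference 1.76, camera adjusted p = 3.18e-13). Fibroblast markers went from 0.25 to -0.24 (-0.52, 0.00227), macrophage markers from 0.22 to -0.29 (-0.47, 3.27e-04) and immediate early genes from -0.24 to 0.15 (0.27, 2.70e-04). For 10% EtOH, matrix genes went from 0.31 to -0.29 (-0.72, 4.53e-06) and macrophage markers from 0.44 to -0.47 (-0.90, 3.01e-08). With 1 surrogate variable, matrix genes after cessation of 10% EtOH turned to 0.17 (camera adjusted p = 0.0374), so this change of side was not kept. Macrophage markers there no longer passed (-0.22, 0.265). With an estimated correlation the adjusted p was 0.785 for the lists of 6% EtOH and 0.917 for those of 10% EtOH, and without control cessation replicate 1 the macrophage difference for 6% EtOH was -0.06 and not past the threshold. The fibroblast difference did not pass without control cessation replicate 1 (-0.36) or 6% EtOH cessation replicate 3 (-0.41), nor the immediate early difference without control cessation replicate 2 (0.06). The ciliated difference was 0.80 without 6% EtOH cessation replicate 1, whose label and count table carry different identifiers.

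Immediate early and cytokine genes were higher in the later controls, with an adjusted p = 0.201 for both lists with an estimated correlation and 0.0226 with fry. A single later control library is argued against, since the immediate early median stayed at 1.28 or more whichever was left out. For the immediate early genes, so is a larger share of stromal cells, vessels and macrophages as the whole cause, if they follow these cells as the markers do. The immediate early level minus that of the 4 marker lists still differed by 1.25 between the control groups (pooled SD 0.362), with no overlap. The markers rose too, by a mean log2 of 1.22 for endothelium, 1.07 for smooth muscle, 0.71 for fibroblasts and 0.76 for macrophages, against 2.19 for the immediate early genes. Such cells may therefore account for part of the rise, which stays open. The cytokine genes were not set against these markers, so for them the whole explanation stays open. Handling of the tissue at the later collection is a candidate explanation, since all 9 libraries after cessation, whatever the dose, lay above the highest library of 10 weeks, but it cannot be told apart from age or time after treatment because every later library was collected at that time. These biological differences were not tested.

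The doses at 10 weeks shared higher complex I genes, a call lost with an estimated correlation (adjusted p = 0.801 for 6% and 0.922 for 10% EtOH) and with fry (0.827 and 0.609), and 10% EtOH passed 1059 genes with the 9 libraries of that time. For complex I, a single library is argued against, since at least 75.9% of its median was kept with any 1 left out. So is a trend with transcript length or GC content as the whole cause. Once each library's trend was removed, the list still passed against all other genes. Its camera adjusted p went from 1.69e-08 to 4.37e-06 with 6% EtOH and from 2.31e-04 to 8.50e-05 with 10% EtOH. Its median kept 100.1% or more, but this has no fixed baseline. With 6% EtOH the correction also moved the TCA cycle from -0.01 to 0.03 and complex IV from 0.13 to 0.11. A part played by such a trend stays open. The correction did end other calls: with 6% EtOH 5 of 17 lists no longer passed, complex IV among them (0.11, adjusted p = 0.152), and with 10% EtOH mitochondrial dynamics (0.06, 0.538). For the 1024 of the 1059 genes with a known length and GC content, 25.4% still passed after that correction (260 genes), as their median absolute log2 fold change fell from 0.556 to 0.381 and 98.8% kept their direction, so a GC trend, with a rho of level with GC across genes from -0.464 (10% EtOH replicate 3) to 0.319 (control replicate 1) at this time, may account for part of the count and stays open. Shared controls stay open for the likeness of the doses, since 12 of 100 draws of unchanged groups reached the observed covariance, and an effect of EtOH stays open beside them.

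Mitochondrially encoded genes were higher with 10% EtOH at 10 weeks, though not past the threshold with an estimated correlation (adjusted p = 0.922) or with fry (0.609). Replicate 3 alone is argued against, since the list kept a median of 0.64 without it (60.8% of its value, adjusted p = 2.27e-04), as are a few abundant nuclear genes, since the 20 most abundant took 2.04 percentage points more of the counts than in controls (pooled SD 0.419, no overlap) where this needs less, and the part of the later tissue state marked by immediate early genes, since these lay at a median of -0.26 in this comparison (pooled SD between libraries 0.293). Once length and GC trends were removed, the list kept 43.4% of its median, which went from 1.05 (pooled SD between libraries 0.423) to 0.45 (0.135) and still passed (adjusted p = 0.00239), so such a trend may account for part of it and stays open. A state of the library that moves its GC trend and its mitochondrial share together is a candidate explanation, since the deviations of both from the group means correlated at r = -0.80 over the 18 libraries (exact permutation p = 0.00894). This correlation cannot tell such a state from the GC trend itself, whose removal lowered the median of these genes. The part of the later tissue state marked by macrophages, fibroblasts and matrix genes stays open, since these were higher here too (0.44, 0.46 and 0.31, against 0.90, 0.86 and 0.98 in the later controls). The level of stromal, macrophage and matrix lists correlated with the share at r = 0.20 within groups (exact p = 0.455, two-sided, n = 18, and r = 0.62 without the 2 libraries farthest out). Among the 9 libraries of 10 weeks r was 0.17 (exact p = 0.694, and r = 0.05 without the 2 farthest out). An effect of EtOH on these transcripts is a hypothesis that this design leaves open, as is a difference in RNA yield or region of the tissue, which was not tested.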

How the results depend on the processing

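The fit of the 9 libraries of 1 time and the removal of length and GC trends were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the labels give the groups no shared replicate numbers. In these alternatives the cause was not tested.

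Named genes kept their direction and their side of the threshold in 6940 of the alternative values, 532 passed where they had not, 64 no longer passed and 32 changed direction without passing on either side. In the main fit genes passed only between the controls, so elsewhere an unchanged side means that a gene passed in neither fit. The named genes were picked by their p or fold change in these same libraries, most of which every planned left-out or refitted setting reused, so the 6940 is not independent support. Gene lists that passed kept both in 628 values, lost their call in 258 and turned in 10.

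Without the low-count filter the genes past the threshold, in place of 0, were 44 and 736 for 6% and 10% EtOH at 10 weeks, 51 and 407 after cessation, 60 and 585 between the doses at the 2 times, 88 and 385 for the difference between times, and 1740 in place of 22 between the controls. DESeq2 gave 73 for 10% EtOH at 10 weeks, 1 for 6% EtOH after cessation, 1 between the doses after cessation, 2 for the time difference of 10% EtOH and 993 between the controls. Voom gave 1345, 66, 4 and 7336 for 10% EtOH at 10 weeks, 10% EtOH after cessation, its time difference and the controls. The compared groups fitted alone gave 35 for 6% EtOH at 10 weeks and 0 for the controls, 1 surrogate variable gave 5 for the controls, and the 9 libraries of 10 weeks gave 1059 for 10% EtOH. Removal of length and GC trends over the 18 libraries gave 46 for the controls and 0 for each comparison with EtOH, and over the 9 libraries of 10 weeks 324 for 10% EtOH. With 1 library left out, counts ranged from 0 to 191 for 10% EtOH after cessation (191 without control replicate 2) and from 0 to 2724 for the controls (2724 without cessation replicate 2); the 1059 ranged from 0 without control replicate 1 or 3 to 1569 without 10% EtOH replicate 2.

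The lists past the threshold for 6% and 10% EtOH at 10 weeks and after cessation (17, 13, 12 and 22) fell to 0 in each with an estimated correlation and with fry. With 1 surrogate variable they were 15, 12, 12 and 17, of which 11, 8, 11 and 13 were among the first. With length and GC trends removed they were 13, 13, 11 and 23, with 5, 1, 1 and 1 lost and 1, 1, 0 and 2 gained. With 1 library left out the first 3 ranged from 9 (without 6% EtOH replicate 2) to 20, from 5 (without 10% EtOH replicate 2) to 17 and from 9 to 22 (without 6% EtOH replicate 2).

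With 1 library left out, medians after cessation of 6% EtOH ranged from -0.22 to 0.11 for the unfolded protein response, -0.33 to 0.12 for beta-defensins, -0.77 to 0.0328 for the interferon response, -0.20 to 0.84 for immediate early genes, -0.48 to 0.0404 for fibroblasts and -0.55 to 0.0917 for macrophages. For immediate early genes after 10% EtOH they ranged from -0.92 to 0.0254. With 1 surrogate variable, matrix genes after 10% EtOH lay at 0.17 and smooth muscle at 0.14.

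The correlation of the doses at 10 weeks was 0.578 without the filter, 0.723 with a stricter filter, 0.849 for genes of a mean log2 CPM of at least 5, and 0.535 to 0.700 with 1 library left out. After cessation it ranged from 0.0644 to 0.623. Between times, for 6% EtOH, it was -0.322 for genes of a mean log2 CPM of at least 5 and ranged from -0.196 to 0.0111; for 10% EtOH it ranged from -0.0565 to 0.213. On simulated counts for 6% EtOH at 10 weeks (18122 genes), edgeR recovered 5.97% of genes changed 1.5 times and 86.4% of those changed 4 times. With the shared spread of the main fit, a small effect on a single gene was thus mostly not detectable. That spread (common 25.4%) exceeded the 11.6% and 14.5% of the 2 groups, so the trial does not show what 3 libraries a group allow at their own spread.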

Other observations

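The counts over other splits of the samples were chosen after the results were seen.

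Rn7sk, a nuclear RNA that restrains transcription elongation and carries no poly(A) tail, took 1.57% to 2.09% of the counts in the 9 libraries of 10 weeks and 1.81% to 3.54% after cessation. The libraries also differed in how expression followed GC content. Across genes, the centred level correlated with GC at rho between -0.476 (10% EtOH cessation replicate 2) and 0.350 (6% EtOH cessation replicate 2). In the fold changes of all 18 libraries the correlation with GC was -0.379 for 10% EtOH at 10 weeks, -0.291 for 10% EtOH after cessation and -0.205 between the controls.

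Regrouping the samples shows how far chance alone reaches. Where no gene passed, genes at an unadjusted p under 0.05 were counted, since any split reaches a count of 0. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For 6% EtOH at 10 weeks the 440 genes were reached by 2 of the 10 splits (highest other 479) and the 17 lists by 3 (highest other 18); with the 9 libraries of 10 weeks, the 1371 genes were reached by the real split alone (highest other 1047). For 10% EtOH at 10 weeks the 2501 genes were reached by the real split alone (highest other 500), as were the 1059 genes past the threshold with the 9 libraries (highest other 0), and the 13 lists by 3 (highest other 18). After cessation of 6% EtOH the 301 genes were reached by 9 splits (highest other 5366) and the 12 lists by 9 (highest other 30), and after 10% EtOH the 1240 genes by 6 (highest other 4594) and the 22 lists by 4 (highest other 27). Between the doses, the 527 genes of 10 weeks were reached by 3 splits (highest other 674) and the 1462 after cessation by 4 (highest other 3601), and between the controls the 22 genes past the threshold by the real split, 1 of the 10 (highest other 0). Other splits after cessation also passed up to 2081 genes between control and 6% EtOH libraries and 540 between the doses, which points to a structure among these libraries that the treatments do not follow. For the differences between times, 27 of 50 drawn splits of 12 libraries reached the 561 genes of 6% EtOH (highest other 3793) and 16 of 50 the 1386 of 10% EtOH (highest other 4216), so chance is not excluded.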
